A study of Homo sapiens with 3 samples.

How the data were processed

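Total RNA from 3 cultures of the human osteosarcoma line MNNG/HOS, a chemically transformed derivative of the HOS line, was measured on NimbleGen one-colour (Cy3) expression arrays, with 1 array per culture. Per the labels' protocols, the cells grew for 5 days in serum-free medium and the floating spheres (sarcospheres) were collected. One culture received no treatment, one received TGF-beta1 at 4 ng/mL, and one was kept under hypoxia, with an oxygen level that is not given in the sources used here. The arrays count as 1 sample per group, so there is no replicate error, no test across samples is possible, and no p-value is given. The words higher and lower describe these 3 arrays only.

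The deposited table holds the authors' intensity values on a linear scale, 1 row per transcript feature and 1 column per array. The background correction, the summary of probes into a feature, the normalization between arrays and any filter are not given in the sources used here. The 3 columns had nearly the same distribution, with medians of 383, 363 and 395 for the untreated, TGF-beta1 and hypoxia arrays, so the table was taken as already normalized. It has 38572 features, against 45033 genes per chip in the series description. No value lies below 50, and 2689 features come within 10% of that value on at least 1 array. If a lower limit was applied on every array, a transcript that was silent in 1 condition would be missing, and a gene near 50 has an understated fold. The table has no detection calls, so whether a dim value exceeds background is unknown. The number of arrays limits the precision.

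Features were named from the platform annotation of the array, with symbols updated through the Entrez identifier (15623 features), and otherwise through an unversioned RefSeq accession match to the annotation of GRCh38.p14 (593 features). The other 22356 features were not named here and entered only the counts that say so. No feature had several symbols. The named features gave 14836 genes, of which 1118 had at least 2 features. The genome build of the array design is not given in the sources used here, so no coordinates are printed.

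Values were log2 transformed with no pseudocount, and a gene's value was the mean over its features. The difference between 2 arrays is a log2 difference. A gene counted as higher or lower where the difference was at least 1 (2-fold) and the brighter of the 2 arrays was at or above that array's median gene value. Hereafter a gene that meets the second condition is called measured above the floor. For 27 gene lists the median log2 difference over all measured members was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and its percentile is given. A percentile describes these arrays. It treats genes as independent and is not a p-value, and 81 percentiles were computed (27 lists in 3 comparisons), of which the central 95% would leave out about 1.35 per comparison by chance. It left out 10 lists for TGF-beta1 minus untreated, 7 for hypoxia minus untreated and 12 for TGF-beta1 minus hypoxia. A place outside it is thus common on these arrays and is weak evidence about any 1 list. Members of a list were counted as higher or lower at 1.5-fold, above the floor.

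Measurement noise was gauged from genes with several features: features of a gene that disagree give an SD per array, in 5 intensity bins. This SD also holds true differences between transcripts and leaves out the variation between cultures. It was used to simulate 100 sets of arrays with no change. Agreement between the first and second feature of a gene was counted after the median difference of all features was subtracted. The procedure was tested on 20 simulated data sets of 14836 genes for TGF-beta1 minus untreated, with 200 genes changed. At a true 2-fold change 49.7% of genes were recovered, which is what a threshold at the true value gives, and at a true 3-fold change 95.3% were. Genes that were not changed gave a mean of 131.6 calls per data set, so many single 2-fold calls on the real arrays can be noise. A shift of 0.5 put into the cell-cycle list was recovered as 0.50, and an unchanged list fell outside the central 95% in 1 of 20 data sets.

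The lists, the thresholds, the processing alternatives and the rule for named genes were fixed before the data were examined. The rule names the 6 largest differences each way per comparison with the untreated array (4 each way for TGF-beta1 against hypoxia) among genes whose features all differ the same way, the 2 largest differences per list above the floor, and the 3 largest each way among genes changed in both comparisons. XIST and Y-linked genes were not named, and some genes that the rule selects are not reported here. RRM2, VEGFA, SMAD7, NANOG, POU5F1, EPAS1, NR4A1, ID1, CDK1, PDK1, PGK1, TXNIP, KIT and the 5 genes that differed in opposite directions were named after their values were seen, as were the genes of the families in the closing section. The alternatives were quantile, median and loess (span 0.3) centring, other floors, other fold thresholds, other ways to join the features of a gene, 16 added before log2, the mean in place of the median, and random lists without matching. Counting every feature was added after the data were seen. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.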

Results

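The expression of MNNG/HOS sarcospheres was compared between untreated spheres, spheres grown with TGF-beta1 and spheres grown under hypoxia. Sarcospheres are floating spheres that form in serum-free medium and are used to enrich for sphere-forming, stem-like sarcoma cells. The log2 intensities of all 38572 features correlated across features at r = 0.974 between hypoxia and untreated, 0.959 between TGF-beta1 and untreated, and 0.956 between TGF-beta1 and hypoxia. Markers of blood and immune cells were dim on all arrays: 1 of 18 measured genes, the lysosomal gene CD68, was above the floor in the TGF-beta1 comparison. None of the 10 endothelial markers and 2 of the 10 neuron and liver markers, SERPINA1 and TUBB3, were above it.

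The first comparison asked which genes differed after TGF-beta1. The TGF-beta1 array showed higher levels of cell-division genes (list median log2 difference 0.71), sterol synthesis genes (0.44), glycolysis genes (0.43) and oxidative phosphorylation genes (0.39). It showed lower levels of matrix genes (-0.29). Interferon-induced genes (-0.47) and stem-cell surface genes (-0.41) also had lower medians, which did not stand apart under every alternative. In total 258 genes were at least 2-fold higher and 307 at least 2-fold lower, among 7950 genes above the floor. Simulated arrays with no change gave means of 73.0 and 58.4 genes in these directions. Under median centring of the arrays the counts were 341 higher and 258 lower, so the balance between the directions depends on the scaling.

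Cell-cycle genes had the largest median difference of the 27 lists. All 44 measured members were brighter on the TGF-beta1 array, with a median log2 difference of 0.71 (1.63-fold), at the 100th percentile of the matched random lists. Of the 42 members above the floor, 29 were at least 1.5-fold higher, 13 were within 1.5-fold and 0 were lower. E2F1, a transcription factor of S-phase entry, stood at 970 against 380 (log2 difference 1.35), and MKI67, the Ki-67 proliferation antigen, at 2278 against 914 (1.32). RRM2, a ribonucleotide reductase subunit, differed by 1.27 and CDK1, the mitotic kinase, by 1.03. The list of CDK inhibitors and p53 targets was at percentile 11.6, with a median of -0.19. Of its 7 members above the floor, 1 was at least 1.5-fold higher, 1 lower and 5 within 1.5-fold. The largest difference was that of BTG2, an antiproliferative p53 target, which stood at 173 against 970. BTG2 was also low under hypoxia, at 243 against the same untreated value. BAX differed by 0.63 with TGF-beta1.

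Metabolic lists were also higher with TGF-beta1. Sterol synthesis genes had a median difference of 0.44 (100th percentile), and 10 of 21 members above the floor were at least 1.5-fold higher with 0 lower. HMGCS1, which makes HMG-CoA, stood at 1497 against 528, and DHCR7, the last enzyme of cholesterol synthesis, differed by 1.26. Glycolysis genes had a median of 0.43 (percentile 99.99), with 6 of 21 members higher, 1 lower and 14 within 1.5-fold. The aldolase gene ALDOC differed by 1.72 and the hexokinase gene HK2 by 1.10. Oxidative phosphorylation genes had a median of 0.39 (100th percentile), with 8 of 42 members higher and 1 lower. The complex I gene NDUFA8 differed by 1.06 and the cytochrome c gene CYCS by -0.89. Reference genes had a median of 0.15 (percentile 87.9), and TFRC, the transferrin receptor, differed by 1.66.

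Genes that TGF-beta induces through SMAD proteins did not stand apart as a list. Their median difference was 0.19 (1.14-fold), at percentile 93.7, and of 24 members above the floor 8 were at least 1.5-fold higher, 3 lower and 13 within 1.5-fold. SPHK1, a sphingosine kinase, stood at 4050 against 1018 (log2 difference 1.99), and BAMBI, a decoy receptor of the pathway, at 178 against 734 (-2.04). SMAD7, the inhibitory SMAD, differed by 0.68. The matricellular protein genes CCN1 and CCN2 differed by 1.56 and 1.04. The BMP/ID list had a median of 0.55 (percentile 99.9) but a mean of 0.12 (percentile 79.7), and 4 of its 14 measured members were above the floor. BMP4 was at 337 against 996, and the BMP antagonist GREM1 at 3576 against 1476.

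Matrix and matrix-remodelling genes had a median difference of -0.29 (percentile 0.04), and 10 of 23 members above the floor were at least 1.5-fold lower against 2 higher. The laminin gene LAMA4 stood at 147 against 806 and the collagen gene COL12A1 at 393 against 1891. Mesenchymal and EMT regulators had a median of 0.21 (percentile 92.5) with members in both directions: the transcription factor PRRX1 differed by 2.16, and the osteoblast cadherin CDH11 by -1.47. Epithelial junction and keratin genes had a median of -0.27 (percentile 4.68), and the keratin gene KRT8 stood at 4193 against 9761. In the osteoblast list, at percentile 40.2, the homeobox gene DLX5 differed by -1.64 and the osteopontin gene SPP1 by -1.14, the latter with an SD of 0.73 between its 3 features and a difference of -0.52 by their median. PPARG, the adipocyte nuclear receptor, differed by -2.18, with an SD of 0.10 between its 2 features.

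Stem-cell surface and drug-efflux markers had a median difference of -0.41 with TGF-beta1 (percentile 0.655), and 4 of 8 members above the floor were at least 1.5-fold lower with 0 higher. CXCR4, the receptor of CXCL12, stood at 139 against 745, and CD24, a surface glycoprotein, at 950 against 3577. KIT, below the floor, went the other way, at 327 against 60.7 (log2 difference 2.43). Of all 15 measured members, 11 were lower and 4 higher. This list was at percentile 5.20 under loess centring and 3.87 under quantile normalization. Pluripotency factors were at percentile 54.5, with 5 of 14 measured members above the floor: MYC differed by 0.97 and SOX2 by -0.80, POU5F1 by 0.67, and NANOG, below the floor, by -0.51. Interferon-induced genes had a median of -0.47 (percentile 0.56), with 5 of 8 members above the floor lower and 1 higher. IFI44 differed by -1.12 and HERC5 by 1.34, and the mean of the list was at percentile 3.22. Angiogenesis genes had a median of -0.34 (percentile 1.26) and a mean of -0.18 (percentile 15.8), with SERPINF1, an angiogenesis inhibitor, at -1.14 and VEGFC, a lymphangiogenic factor, at 0.98. Immediate-early genes had a median of -0.30 (percentile 1.46, and 3.11 without matching on expression) and a mean of -0.27 (percentile 4.81), but only DUSP1, a MAP kinase phosphatase, was at least 1.5-fold lower among 11 members above the floor, against 2 higher.

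The other lists lay inside the central 95% of random lists with TGF-beta1. Unfolded-protein and integrated stress response genes were at percentile 89.1, with CHAC1 at 1.15 and ASNS at 0.87. Notch and Wnt targets were at percentile 71.7, with HEYL, a Notch target, at 704 against 91.0 and LEF1 at 1.17. Heat-shock genes were at percentile 57.1, with HSPH1 at 1.17 and HSPD1 at 0.91. Cytokine and NF-kB genes were at percentile 45.7, with LIF, a cytokine of the IL-6 family, at 4095 against 1365. Ribosomal protein genes were at percentile 82.7 (RPS19 at 0.63), chondrocyte and adipocyte genes at percentile 45.7 (COL2A1 at -0.78) and HIF/hypoxia-induced genes at percentile 15.6, with CA12 at -0.97 and PFKFB3 at 0.87.

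Among genes whose features all differ the same way, the largest increases included those of STXBP6, CMKLR2, TRIM40, FZD9 and CNTN5. These genes stood between 53.1 and 68.9 on the untreated array, close to the lowest value of the table, and between 462 and 710 on the TGF-beta1 array. The largest decreases included that of AOAH (NM_001637), which codes for acyloxyacyl hydrolase, from 1177 to 52.4. APOD (apolipoprotein D) stood at 133 against 1606, EDIL3 at 84.0 against 932, SELENOP (selenoprotein P) at 85.6 against 890.5, GJA9 at 63.2 against 564 and ARRDC4 at 67.8 against 594. With no detection calls, the size and order of differences from values this near 50, in either direction, are not settled. Each of these genes has 1 feature in the table. Where a gene had several features and the first was at least 2-fold higher with TGF-beta1, the second was at least 1.5-fold higher in 14 of 22 genes. For decreases this held in 18 of 23 genes.

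**Figure D1:**
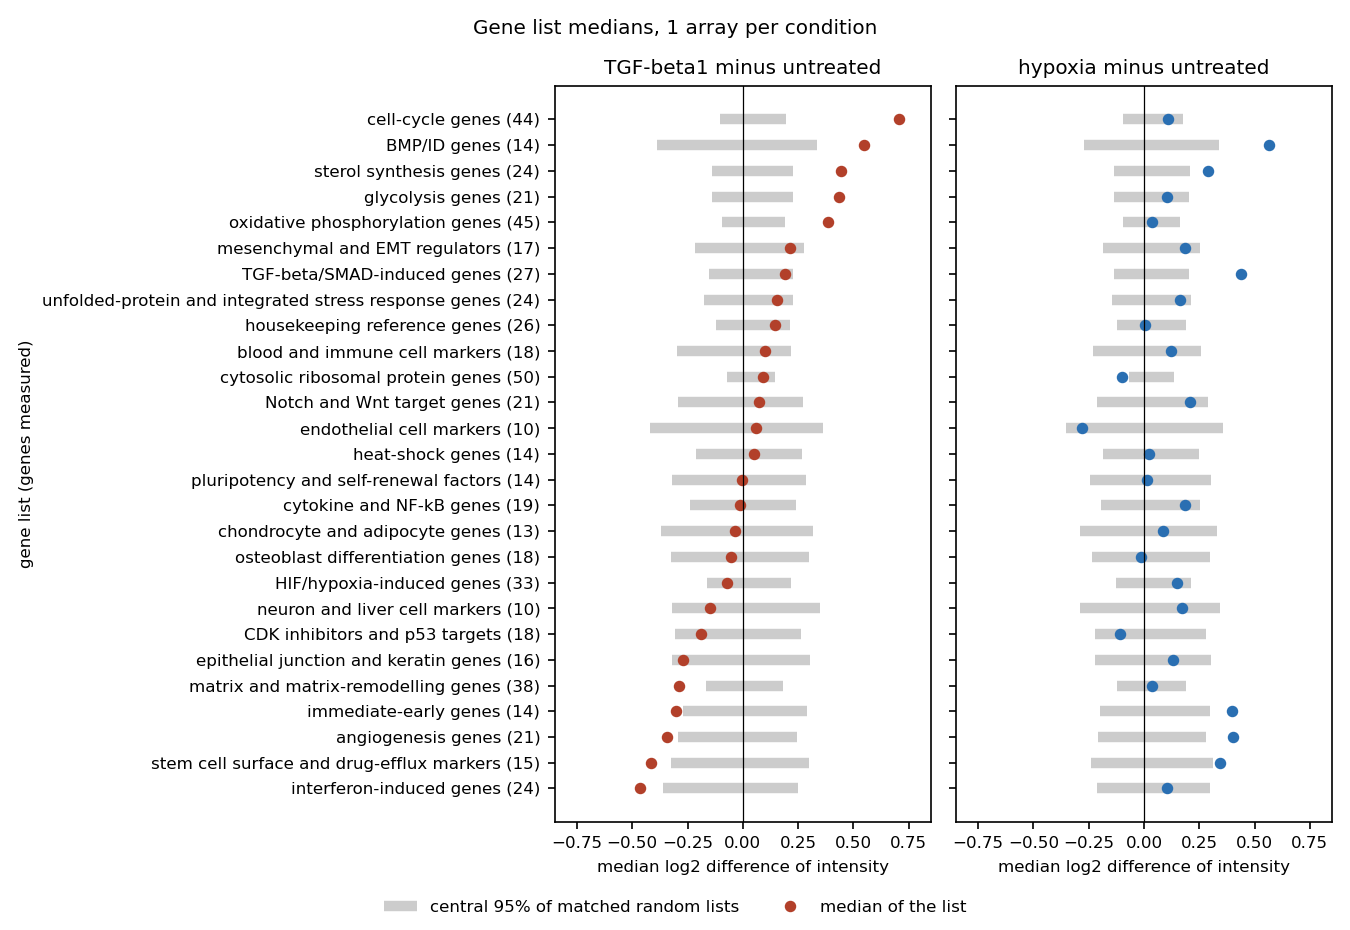
Median log2 difference of intensity for each of 27 gene lists (vertical axis, with the number of genes measured), for TGF-beta1 minus untreated (left, red) and hypoxia minus untreated (right, blue). Grey bars span the central 95% of the medians of matched random lists. With 1 array per condition there is no replicate error. Cell-cycle genes lie at 0.71 on the left and 0.11 on the right.

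The second comparison asked which genes differed under hypoxia, and it gave fewer and smaller differences. The hypoxia array showed higher levels than the untreated array of BMP/ID genes (list median log2 difference 0.57), TGF-beta/SMAD-induced genes (0.44), immediate-early genes (0.40) and sterol synthesis genes (0.29). The BMP/ID and sterol synthesis medians were also higher with TGF-beta1, at 0.55 and 0.44, against the same untreated array. For TGF-beta1 minus hypoxia they were -0.09 (percentile 42.4) and 0.26 (percentile 98.8). A low reading of the untreated array thus cannot be excluded for these lists. The angiogenesis (0.40) and stem-cell surface (0.34) lists had higher medians, but 1 member of each was at least 1.5-fold higher and neither list stood apart by its mean. In total 129 genes were at least 2-fold higher and 77 at least 2-fold lower, among 7820 genes above the floor. Simulated arrays with no change gave means of 24.6 and 37.4 genes.

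Genes induced by hypoxia through HIF did not stand apart by their median, 0.15 (1.11-fold), at percentile 89.5. Their mean, 0.28, was at percentile 99.9, since a few members differed by much more than the rest. Of 27 members above the floor, 7 were at least 1.5-fold higher, 0 lower and 20 within 1.5-fold. ANGPTL4, an angiopoietin-like secreted protein, stood at 645 against 156 (log2 difference 2.04), and ADM, the vasodilator adrenomedullin, at 1424 against 626 (1.19). VEGFA, the vascular growth factor, differed by 0.54, and PDK1, a pyruvate dehydrogenase kinase, by -0.51. Glycolysis genes had a median of 0.11 (percentile 81.4), with 3 of 20 members above the floor higher and 0 lower. ALDOC differed by 1.07, PFKM (phosphofructokinase) by 0.72 and PGK1 (phosphoglycerate kinase) by -0.47. Oxidative phosphorylation genes were at percentile 51.8, with NDUFB3 at 0.73 and COX6C at -0.71.

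TGF-beta/SMAD-induced genes had a median difference of 0.44 (1.35-fold) under hypoxia, at the 100th percentile. Of 23 members above the floor, 9 were at least 1.5-fold higher, 1 lower and 13 within 1.5-fold. CCN1 stood at 4918 against 1337 and CCN2, another matricellular protein, at 2057 against 592. Both were also at least 2-fold higher with TGF-beta1. Above the floor, 4 members were at least 2-fold higher and 2 lower with TGF-beta1, against 3 and 0 under hypoxia. BMP/ID genes had a median of 0.57 (percentile 99.95), and 5 of 7 members above the floor were higher with 0 lower. ID3 differed by 1.58, BMP4 by 1.37 and ID1 by 1.27. All 14 immediate-early genes were brighter under hypoxia, with a median of 0.40 (percentile 99.7). FOSB differed by 1.84, MYC by 1.64 and NR4A1 by 1.33, and 4 of 11 members above the floor were at least 1.5-fold higher.

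Angiogenesis genes had a median of 0.40 (percentile 99.9), but 1 of 10 members above the floor, ANGPTL4, was at least 1.5-fold higher, and the list's mean of 0.15 was at percentile 83.7. Stem-cell surface markers had a median of 0.34 (percentile 98.6), but 1 of 8 members above the floor, CXCR4 at 1624 against 745, was at least 1.5-fold higher, and 7 were within 1.5-fold. The endoglin gene ENG differed by 0.55. The mean of this list, 0.13, was at percentile 78.1. Sterol synthesis genes had a median of 0.29 (percentile 99.9), with 3 of 22 members above the floor higher and 0 lower, and DHCR7 at 0.86. Cell-cycle genes had a median of 0.11 (percentile 84.7), with CENPA, the centromeric histone, at 0.69 and MCM4, a replicative helicase subunit, at -0.71. Ribosomal protein genes had a median of -0.10 (percentile 0.79), with 47 of 48 members within 1.5-fold and RPS6 at -0.98. This list was at percentile 3.60 without matching on expression, and at 23.9 among genes with 2 or more features of the same sign. In the matrix list, at percentile 49.7, COL3A1 differed by -1.25 and the collagenase gene MMP1 by 1.11.

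The other lists lay inside the central 95% of random lists under hypoxia. Unfolded-protein and integrated stress response genes were at percentile 92.4, with DDIT3, the stress transcription factor CHOP, at 1.13 and CHAC1 at 0.80. Cytokine and NF-kB genes were at percentile 92.2, with LIF at 1.34 and ICAM1 at 0.78, and Notch and Wnt targets at percentile 90.8, with HEY1 at 1073 against 2154. Mesenchymal and EMT regulators were at percentile 90.5, with SNAI1 at 0.94 and LEF1 at -0.86. Epithelial genes were at percentile 75.6 (DSP at -0.80), interferon-induced genes at percentile 69.1 (IFI44 at -0.69 and OASL at 0.66), chondrocyte and adipocyte genes at percentile 68.5 (COL2A1 at -0.46), pluripotency factors at percentile 47.5 (KLF4 at 0.61), heat-shock genes at percentile 45.3 (HSPH1 at 0.80), osteoblast genes at percentile 36.9 (COL1A1 at -0.84 and SPP1 at 0.66), reference genes at percentile 31.3 (CHMP2A at 0.61) and CDK inhibitors and p53 targets at percentile 12.8 (GADD45A at 0.49).

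The largest increases under hypoxia were those of KRT83 (2.75), PRR16 (2.45), GDF15 (2.39), CPTP (2.36), SMOC1 (2.32) and DKK1 (2.31). Apart from GDF15, these genes stood between 81.7 and 144 on the untreated array. With no detection calls, the size and order of differences from values this dim are not settled. GDF15, a stress-induced cytokine, stood at 1647 against 315, and DKK1, a Wnt antagonist, at 556 against 112. KRT83 has near-identical hair keratin paralogs, so its signal can be shared with them. The largest decreases were those of KCNJ13 (-2.28), MFAP4 (-2.20), BTG2 (243 against 970), ARRDC4 (-1.84), SPACA5 (-1.78) and GPR50 (-1.72). KCNJ13 stood at 91.9 on the hypoxia array, GPR50 at 144, SPACA5 at 146 and ARRDC4 at 165, so the order of the decreases is not settled either. MFAP4, a microfibril-associated matrix protein, stood at 1327 against 6098. Where a gene had several features and the first was at least 2-fold higher under hypoxia, the second was at least 1.5-fold higher in 6 of 12 genes.

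**Figure D2:**
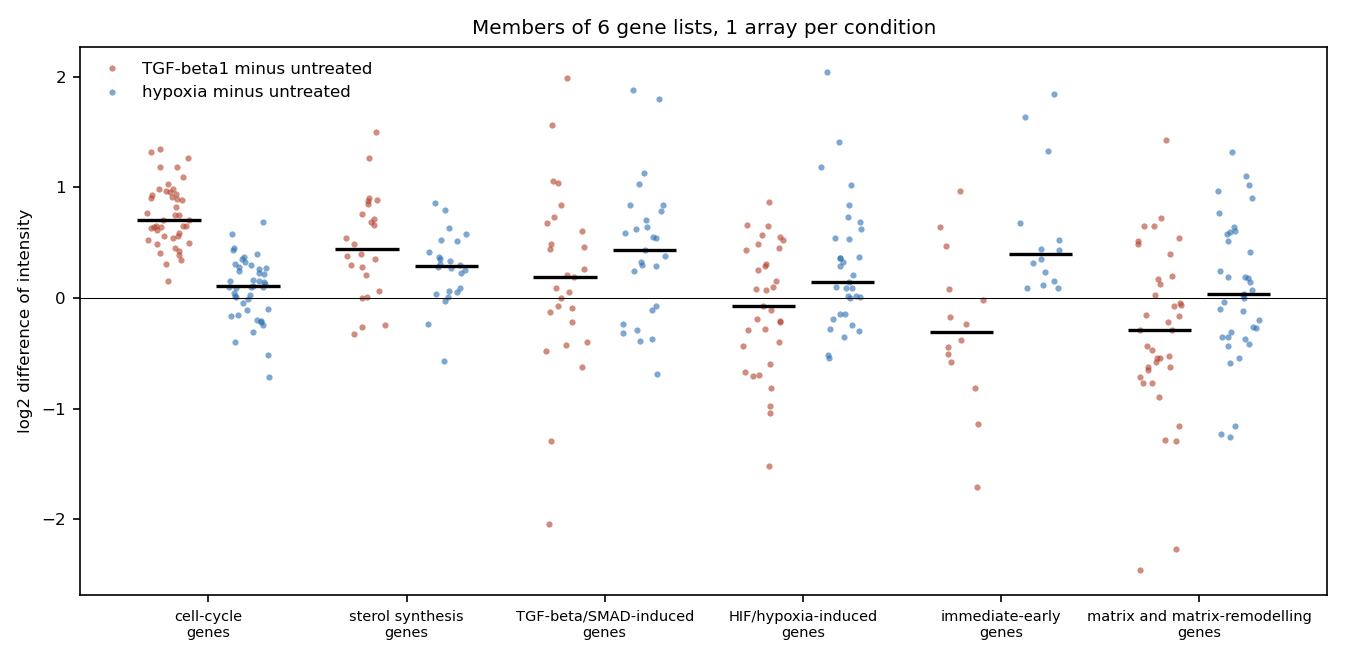
Log2 difference of intensity (vertical axis) for each measured member of 6 gene lists, for TGF-beta1 minus untreated (red) and hypoxia minus untreated (blue). Each point is 1 gene and the black line is the list's median, 0.71 and 0.11 for cell-cycle genes and -0.30 and 0.40 for immediate-early genes.

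The third comparison set TGF-beta1 directly against hypoxia, without the untreated array. Cell-cycle genes were higher with TGF-beta1 here too, with a median of 0.68 (100th percentile) and all 44 members brighter. This rests on the same TGF-beta1 array as the first comparison, so it is not an independent second observation. Immediate-early genes were lower with TGF-beta1, with a median of -0.67 (percentile 0.04) and 13 of 14 members dimmer. HIF/hypoxia-induced genes were lower with TGF-beta1 than under hypoxia, with a median of -0.28 (percentile 1.12). The median of TGF-beta/SMAD-induced genes was -0.22 (percentile 2.54), and thus not higher with TGF-beta1. Reference genes had a median of 0.24 (percentile 99.1) and ribosomal protein genes of 0.18 (percentile 99.4), so reference genes also stood apart between these arrays. In total 259 genes were at least 2-fold higher with TGF-beta1 and 455 lower. Median centring, which moved the median of all genes from -0.03 to 0.09, gave 415 higher and 333 lower. The largest differences in favour of hypoxia were those of GDF15 (1647 against 109), GLDN (1931 against 158), ANGPTL4 (645 against 54.8) and CXCR4 (1624 against 139). Those in favour of TGF-beta1 were CMKLR2 (710 against 58.8), STXBP6 (661 against 59.5), VWA5B1 (556 against 53.4) and TRIM40 (616 against 60.1). The order among these genes is not settled, since the dimmer values lie near the lowest value of the table or are not known to exceed background.

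Some genes were shared by both inductions. At least 2-fold higher in both were 19 genes, out of 258 with TGF-beta1 and 129 under hypoxia, led by SIK1, CCN1 and PAEP. At least 2-fold lower in both were 30, out of 307 and 77, led by AOAH, ARRDC4 and BTG2. PAEP differed by 1.41 with TGF-beta1 and 1.79 under hypoxia, with SDs of 0.85 and 0.78 between its 2 features, and by its brightest feature it differed by 0.81 and 1.24, under 2-fold with TGF-beta1. Independent lists of these sizes would share 1.53 and 3.11 of the 7612 genes above the floor in both comparisons. Simulated unchanged arrays that share 1 untreated array gave 3.45 and 10.7. The simulated lists were smaller, with means of 73.0 and 24.6 genes higher and 58.4 and 37.4 lower. Their overlaps thus do not show what lists of the observed sizes would share through the untreated array alone. The untreated array cannot be split, so how much of the observed overlap comes from it is not known. The log2 differences of the 2 comparisons correlated at 0.33 across all 14836 genes, which are not independent replicates, against 0.39 in the simulation, and their covariance was 0.101 against 0.0814. No gene was higher with TGF-beta1 and lower under hypoxia. The reverse held for 5 genes, against 3.35 for independent lists. The simulation gave 0, but from smaller lists and a shared untreated array, so this 0 is no yardstick for the 5 genes. These 5 genes were CXCR4, BMP4, the drug transporter gene ABCC3, the retinol dehydrogenase gene RDH10 and ZG16B. Under hypoxia ABCC3, RDH10 and ZG16B differed by 1.03, 1.04 and 1.01, barely past the threshold of 1, so a small change of scaling could remove them.

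**Figure D3:**
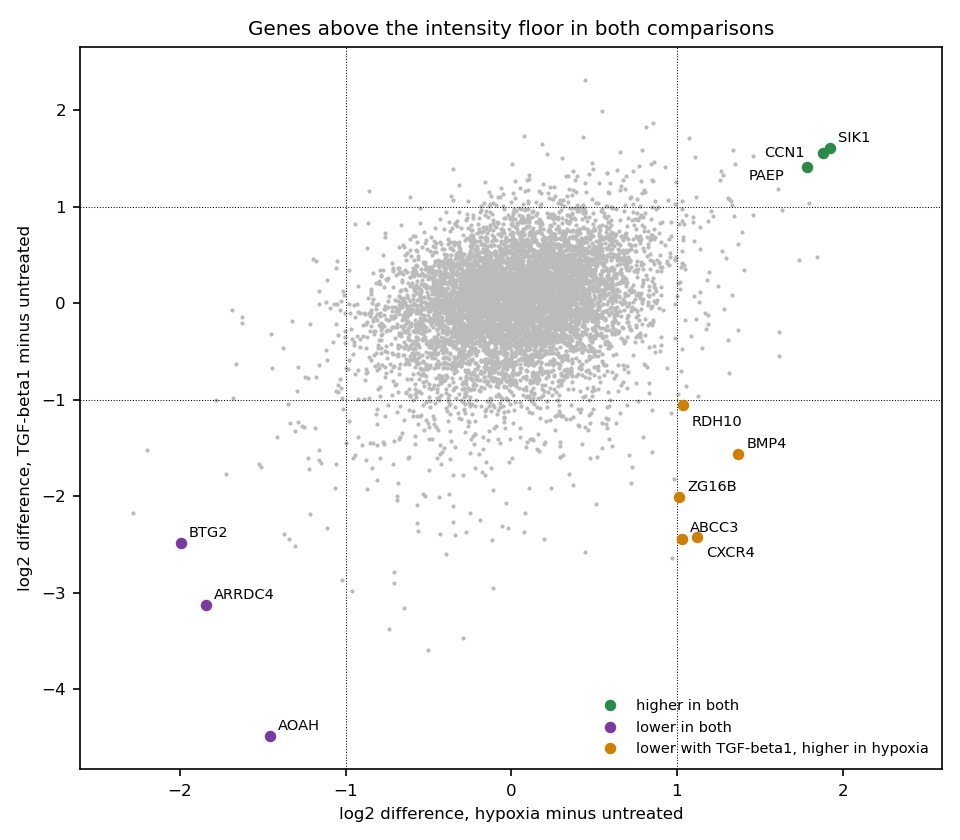
Log2 difference of TGF-beta1 minus untreated (vertical axis) against hypoxia minus untreated (horizontal axis) for the 7612 genes above the intensity floor in both comparisons. Each point is 1 gene, dotted lines mark a 2-fold difference, and coloured points are the leading genes higher in both (green), lower in both (purple) and the 5 genes lower with TGF-beta1 and higher under hypoxia (orange). Both axes share the untreated array, so a positive slope arises with no effect.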

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

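Counting every feature was an alternative chosen after seeing the data. With 1 array per condition no array can be left out, and no paired analysis was possible because each group has 1 array. No list outside the central 95% of random lists, and no named gene with a difference of at least 1, changed sign under any alternative that gave a value. Of 653 list values recomputed, 612 moved by less than the SD of matched random lists, and of 859 values of named genes 856 stayed within the noise SD. The order of counts below is higher and lower for TGF-beta1 minus untreated, then hypoxia minus untreated, then TGF-beta1 minus hypoxia, then higher and lower in both; the reported values were 258, 307, 129, 77, 259, 455, 19 and 30. Without a floor they were 648, 807, 418, 328, 646, 1003, 92 and 114. With the floor at the 75th percentile they were 63, 90, 37, 15, 88, 173, 3 and 8. With a 1.5-fold threshold they were 998, 912, 676, 445, 1047, 1213, 163 and 140, and with a 3-fold threshold 56, 92, 25, 11, 53, 135, 1 and 4. Restricted to genes with 2 or more features of the same sign they were 11, 23, 5, 2, 8, 32, 1 and 2, since few genes have 2 features. Counting every feature gave 655, 965, 359, 265, 694 and 1276. The floor and the thresholds change the counts by their construction. Median centring gave 415 genes higher with TGF-beta1 than under hypoxia. Quantile, loess and median centring each kept the other counts within 1.5 times. The HIF/hypoxia-induced list had a mean of 0.28 under hypoxia against a median of 0.15. Its percentile ranged from 86.4 to 89.5 under the alternatives that keep the median. The lists for cell-cycle, sterol synthesis, glycolysis, oxidative phosphorylation and matrix genes with TGF-beta1, and for TGF-beta/SMAD-induced, BMP/ID, immediate-early and sterol synthesis genes under hypoxia, stayed outside the central 95% of random lists in every alternative that gave a value. The stem-cell surface, angiogenesis, immediate-early, interferon and BMP/ID lists with TGF-beta1 did not in 1 or 2 of 8 alternatives each, and neither did the angiogenesis and stem-cell surface lists (1 of 8) and the ribosomal list (2 of 9) under hypoxia. For TGF-beta1 minus hypoxia the mesenchymal and EMT list lost its place in 4 of 8 alternatives, and the epithelial and angiogenesis lists in 2 of 8 each. Lists with fewer than 5 members of 2 or more features gave no value there.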

Other observations

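Of 13 gene families outside the planned lists, several stood apart, and 5 are described. The families were chosen after the data were seen, as were the tests of a low reading of the untreated array, its simulated ratio, and the test of single cultures. IGFBP genes, which bind insulin-like growth factors, had a median log2 difference of -0.97 with TGF-beta1 over 7 measured genes: IGFBP3 differed by -1.92, IGFBP6 by -1.49, IGFBP4 by -1.18 and IGFBP7 by 0.91. Under hypoxia this family's median was 0.26 (percentile 88.9), with IGFBP1 at 1.21, IGFBP5 at 1.13 and IGFBP3 at -0.87. Metallothionein genes, which bind metals, had a median of -0.82 with TGF-beta1 and -0.30 under hypoxia over 10 measured genes, with MT1F at -1.86 and -0.69 and MT2A at -0.15 and -0.20; these genes are near-identical copies, so their signals can be shared. Genes of the mitochondrial ribosome had a median of 0.31 with TGF-beta1 (77 genes), led by MRPL41 at 1.38. Histone genes, also near-identical copies, had a median of -0.29 under hypoxia (74 genes, 0 of 49 above the floor at least 1.5-fold higher and 12 lower) and of -0.18 with TGF-beta1 (5 of 51 higher and 7 lower). TXNIP, a glucose-responsive arrestin-like gene, differed by -2.45 with TGF-beta1 and -1.34 under hypoxia, and its relative ARRDC4 stood at 67.8 and 165 against 594. The directions of the medians given for the IGFBP, metallothionein, mitochondrial ribosome and histone families held under quantile, median and loess scaling, but the histone median with TGF-beta1 was -0.10 under median centring. EPAS1, which codes for HIF-2 alpha, differed by 1.62 under hypoxia. Olfactory receptor genes, with 0 of 126 above the floor, had a median of 0.16 for TGF-beta1 minus hypoxia, at percentile 100 of matched random lists. An extreme percentile thus also arose for a family whose members were all dim.

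The higher cell-cycle genes on the TGF-beta1 array had the largest median of the planned lists in that comparison, and TGF-beta is better known as a growth inhibitor of epithelial cells. Removing a trend with intensity left the median at 0.72 (loess centring). Noise that is independent between genes was argued against by the list's percentile of 100 among matched random lists. The list was singled out by this same median, and the percentile does not address error that genes share. The dim olfactory receptor family also reached 100, for TGF-beta1 minus hypoxia. A low reading of the untreated array was argued against because the median under hypoxia was only 0.154 of that with TGF-beta1, though both use that array. A difference between single cultures, such as sphere size or density, cannot be told apart from TGF-beta1 with 1 array per group, so a TGF-beta1 effect stays open, as untested.

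The TGF-beta1 array held 12 genes at or above its median that were at or below the 25th percentile on both other arrays, among them HEYL, STXBP6, CMKLR2, TRIM40, FZD9 and CNTN5, against 1 for the untreated array and 0 for the hypoxia array. It also held 10 genes that were low on this array alone, among them AOAH, EDIL3, SELENOP and PPARG. More noise on this array could give such genes. The SD between features of a gene was largest on the TGF-beta1 array in bins 1 to 3, the dimmest of the 5 intensity bins. In bin 1 it was 0.54, against 0.37 (untreated) and 0.43 (hypoxia), and in bin 2 0.45, against 0.40 and 0.24. In the brighter bins 4 and 5 it was largest on the hypoxia array. For genes with several features the second feature followed a 2-fold increase by at least 1.5-fold in a share of 0.636 of 22 genes against the untreated array, a value between the bounds set beforehand, and against the hypoxia array in 0.406 of 32 genes, below the bound for noise, so noise and a true change cannot be told apart for the genes that were high alone. For decreases against the untreated array, for which no bounds were set, the share was 0.783 of 23 genes, and PPARG was low on both of its features.

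The leading genes of the hypoxia array included CCN1, CCN2, DKK1, FOSB, MYC and GDF15, several of which are known targets of YAP/TEAD or serum-response signalling. A low reading of the untreated array could account for part of the higher values under hypoxia. The 129 genes at least 2-fold higher under hypoxia had a median of 0.34 with TGF-beta1 against 1.21 under hypoxia, a ratio of 0.280. Both use the untreated array, and simulated unchanged arrays gave ratios of 0.189 to 0.648 (mean 0.435). The simulated lists were smaller, with a mean of 24.6 genes, so this range is no yardstick for 129 genes. The ratio of 0.280 thus decides nothing. A wider set of 19 YAP/TEAD targets outside the leading genes already seen was at percentile 94.9 (median 0.25) under hypoxia, short of the bound set beforehand. Of its 13 members above the floor, 1 was at least 1.5-fold higher and 2 lower. Both explanations stay open.

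Of the 22356 features without a name here, 11545 were above the floor for TGF-beta1 minus untreated, with the floor taken over all features. Of these, 345 (2.99%) were at least 2-fold higher and 593 (5.14%) lower. For hypoxia minus untreated 11431 were above it, with 199 (1.74%) higher and 166 (1.45%) lower.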
